A study of Mus musculus with 2 samples.

How the data were processed

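Gene expression was measured in the mouse cell line 1F9, which came from a thymoma of an E2A-deficient animal and so lacks E12 and E47, the helix-loop-helix transcription factors made from the E2A gene. The cells had been infected with one of 2 retroviruses. One virus carried E47 fused to an oestrogen receptor part (E47-ER), which makes the fusion protein inducible by 4-hydroxytamoxifen. The control virus carried the bHLH region of E47 fused in the same way, without the N-terminal activation domain (bHLH-ER). Per the labels, infected cells were given 4-hydroxytamoxifen for 6 hours starting 1 day after infection, were selected with magnetic beads for the human CD25 marker that both viruses encode, and gave RNA for 1 single-colour (Cy3) oligonucleotide array per construct. The group of each array was taken from the sample titles. The free-text descriptions of both samples name the E47 fusion, so only the titles and the source name of the E47-ER sample tell the constructs apart.

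The deposited table holds 1 intensity per probe and array for 20289 probes. The intensities deposited by the authors are on a linear scale. They range from -0.0829 to 529 on the control array and from -0.0609 to 555 on the E47-ER array. Their medians are 0.950 and 0.939, so they had been background-subtracted and scaled by the authors before deposit. The scanner, the background method and the exact scaling are not given in the sources used here. The table carries no detection calls and no marks for control spots. With 1 array per construct, precision is limited by the number of arrays, and no p-value or standard error for the constructs can be given.

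A value was missing for 173 probes on the control array and 177 on the E47-ER array. Another 346 and 180 probes, respectively, were at or below 0. In all, 668 probes lacked a positive value on at least 1 array and were left out, which kept 19621. Log2 intensities were centred on each array's median over these probes. Because no probe is marked as a control, none was left out of that median. Gene symbols came from the platform's annotation, with symbols looked up by Entrez gene ID in the RefSeq annotation of GRCm38.p6. A single symbol was found for 10349 probes (10208 distinct symbols), none had several, and 9940 probes are unnamed here. No coordinates are given, since no genome build is named for the array. Probes of one gene were averaged on the log2 scale. Genes whose mean log2 level over both arrays reached the median of all probes were called measured. There were 5563 of them, and the limit corresponds to an intensity of about 1.03.

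The difference reported for a gene is its centred log2 intensity on the E47-ER array minus that on the control array. A gene was called higher or lower at 2-fold or more. The only repeat measurements within the arrays were different probes of one gene. Over 39 measured genes with several probes, their log2 differences had a pooled SD of 0.21 (95% interval 0.17 to 0.27), which includes probe design and spot error but not the spread between cultures. Among probes above the level limit the robust SD of the log2 difference within level bins lay between 0.18 and 0.28, against 2.33 in the dimmest of 20 bins.

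For 24 gene lists, the median log2 difference of the measured members was placed among the medians of 10000 random lists of measured genes, of the same size and matched on mean level in 20 bins. Lists with fewer than 3 measured members got no percentile, which left 21. Percentiles below 2.5 or above 97.5 are called outside the central 95%. About 1.05 of 21 lists would be outside by chance. Members of a pathway vary together, so the percentile describes these 2 arrays and is not a p-value. The settings, lists and alternatives were fixed before the data were examined, apart from the alternatives said to be added later. The named genes are the 12 with the largest and the 12 with the smallest difference, leaving out predicted and clone-only symbols. From each list, up to 3 members past 2-fold per direction are also named, or the member with the largest difference where none passed. Tcf3, Il2ra, Esr1, Id1, Id2, Id3, Cdk6, Socs1, Socs3, Ptcra, Rag1, Rag2, Il7r, Gfi1 and Notch1 are named in every case. Other members given as examples were chosen after their values were seen.

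The procedure was tested on simulated arrays with the levels of these 2 arrays, the 5563 measured genes and 200 changed genes, in 4 groups of 50. The noise was normal, independent between probes, and had the robust SD of each level bin. It thus holds no heavier tails and no noise shared between genes. The 2-fold rule called 6% of genes with a true 1.5-fold change, 56% of those with a 2-fold change, 98% with a 3-fold change and 100% with a 4-fold change. It also called 3 of 5363 unchanged genes. Of 100 unchanged lists of 15 genes, 2% fell outside the central 95%, and a list shifted by 0.3 on the log2 scale was placed at the 99.95th percentile. The unchanged lists were drawn at random from the simulated genes, so their rate says nothing about lists whose members vary together.

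Alternatives were other scalings (no centring, the 75th percentile, quantile normalization, loess on level with a span of 0.4), other level filters, the brightest probe per gene, a floor at the 25th percentile, and other size rules (1.5-fold, 3-fold and 2.5 times the local spread). Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.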

Results

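Expression profiles of 1F9 thymoma cells were compared 6 hours after activation of E47-ER or of the bHLH-ER control, to find genes that respond to E47 in cells without endogenous E2A proteins. Each construct was represented by 1 array, so no difference below has a replicate check. No array of uninfected or untreated cells is part of the study, so a difference may come from either construct. Of the 20289 probes, 19621 had a positive intensity on both arrays, and 5563 named genes were measured above the level limit. The median intensity of all probes was 0.950 on the control array and 0.939 on the E47-ER array, and the 75th percentiles were 6.19 and 6.61. The genes above the level limit had a median log2 difference of 0.11, so a gene at 0 lies slightly below the middle of this set. Where a fold is given, the scaled intensities behind it are given for the main genes, in the order control array and E47-ER array.

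More genes were higher than lower with E47-ER: 75 measured genes were at least 2-fold higher and 15 at least 2-fold lower, together 1.62% of those measured. Among the 75, 10 were at least 4-fold higher, whereas no gene was 4-fold lower. Grasp (Entrez gene 56149), a scaffold protein, had the largest difference, at 7.01-fold (0.680 and 4.72, the former below the level limit). Id2 (Entrez gene 15902), an inhibitor that dimerises with E proteins and blocks their DNA binding, was 6.65-fold higher and was bright on both arrays (24.2 and 160). The tyrosine phosphatase gene Ptpre was 5.78-fold higher (1.03 and 5.91). Nkd1, which encodes an inhibitor of Wnt signalling, was 4.91-fold higher (1.10 and 5.33). The control intensities of both lay near the level limit. Setting the arrays' 75th percentiles equal changed the split from 75 and 15 to 52 higher and 24 lower genes, and shifted all measured genes by -0.11.

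The other genes among the 12 with the largest increase were Arpp21 (4.65-fold), the adhesion receptor gene Adgrg1 (4.48-fold), Socs3 (4.40-fold), Il10 (4.33-fold), Ptcra (4.25-fold), the small heat shock protein gene Hspb3 (4.03-fold), Il21r (3.88-fold) and the neurotrophic factor gene Nrtn (3.81-fold). Arpp21 went from 10.9 to 50.2 and the cytokine gene Il10 from 6.79 to 29.1. Hspb3, Socs3 and Il21r had control intensities of 0.715, 0.764 and 0.907, under the level limit of 1.03.

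**Figure D1:**
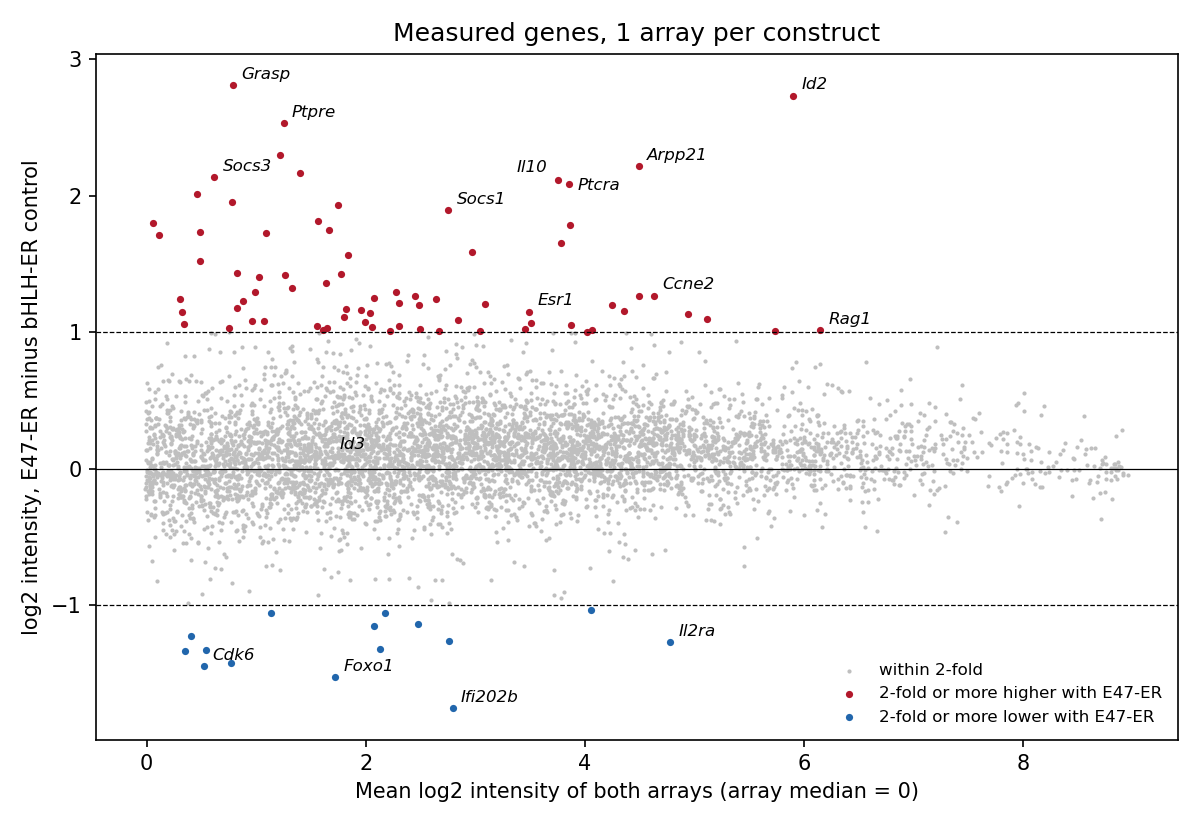
Log2 difference between the E47-ER and bHLH-ER arrays (vertical axis) against the mean log2 intensity of both arrays (horizontal axis, array median at 0) for the 5563 measured genes, 1 point per gene and 1 array per construct. Dashed lines mark 2-fold. The 75 genes in red lie above and the 15 in blue below, and Id2 stands out among bright genes.

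Lower genes had smaller folds. The largest decrease was that of the interferon-inducible gene Ifi202b (Entrez gene 26388), at 3.38-fold (13.3 and 3.90); it belongs to a family of closely related genes whose transcripts a probe may share. Foxo1, a forkhead transcription factor, was 2.88-fold lower (5.83 and 2.003) and Cdk6, a G1 cyclin-dependent kinase, 2.73-fold lower (2.48 and 0.899). The deubiquitinase gene Mindy2 was 2.69-fold lower. Tox, which encodes a nuclear factor of developing T cells, was 2.52-fold lower. Ms4a6b and Ms4a4b, members of one family of membrane proteins, were 2.53-fold and 2.197-fold lower. Il2ra, the mouse interleukin 2 receptor alpha chain (CD25), was bright and 2.41-fold lower (44.4 and 18.2). Both viruses encode human CD25, and whether the Il2ra probe also detects that transcript is not given in the sources used here. The others among the 12 were Slc46a3 (2.51-fold), Fxyd5 (2.40-fold), Camkk2 (2.34-fold) and Pdgfrb (2.23-fold). On the E47-ER array Tox (0.948), Ms4a6b (0.827), Camkk2 (0.895) and Cdk6 were under the level limit.

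The introduced construct could be checked only in part. No probe is named Tcf3, the gene that encodes E47, in the annotation used here, and the same holds for Id1 and Notch1. The probe named Esr1, the oestrogen receptor alpha gene, was 2.22-fold brighter with E47-ER (7.87 and 17.3). Whether it detects the receptor part of the fusion transcripts is not given in the sources used here, and both viruses carry such a part.

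The median of the pre-TCR and TCR signalling list lay above that of matched lists, while 14 of its 16 measured members were within 2-fold. Of 16 measured members of the pre-TCR and TCR signalling list, 12 had positive differences, 2 were at least 2-fold higher and none was 2-fold lower. Ptcra, the pre-TCR alpha chain, went from 7.32 to 30.8, and Prkcq, a protein kinase C of T cells, was 2.02-fold higher. Cd8b1 had a difference of 0.86, Lcp2 of 0.71 and Cd3g of 0.61. The negative members were Cd3e (-0.47), Vav1 (-0.18), Zap70 (-0.18) and Cd28 (-0.03), and Cd247 stood at 0.06. Under 75th percentile scaling 11 of the 16 differences were positive. The list median of 0.39 was at the 99.98th percentile of matched random lists, whose medians centred on 0.12. All 7 measured genes of V(D)J recombination and end joining had positive differences, with a list median of 0.40 (99.47th percentile), which was 0.74 with the level filter at the 75th percentile. Rag1 was 2.02-fold higher (52.1 and 104) and Rag2 1.81-fold higher (8.37 and 15.02); these genes encode the recombinase. Dntt, the terminal transferase, had a difference of 0.40. Rag1 and Prkcq lie just past the 2-fold rule, and with the 75th percentile scaling they fell to 0.91 and 0.90.

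Id proteins and other bHLH factors did not move as a group: the list median of 0.17 over 11 measured genes lay at the 77.2nd percentile. Beside Id2, Mxd4, a partner of Max, was 2.16-fold higher. Id3 had nearly equal intensities of 3.25 and 3.44, a 1.07-fold difference. The E protein genes Tcf4 and Tcf12 had differences of -0.76 and -0.33. In the Notch pathway none of 13 measured genes passed 2-fold, and the list lay at the 66.4th percentile; the largest difference was that of the receptor gene Notch3 (1.77-fold higher). 

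Transcription factors of the T lineage differed in both directions, with a median below that of matched lists. Of 17 measured members, Ets2 (2.97-fold) and Gfi1 (2.205-fold), which encodes a zinc-finger repressor, were higher. Foxo1 and Tox, given above, were lower, and 13 were within 2-fold. Among the latter were Gata3 (-0.98, but -1.09 and so past 2-fold under 75th percentile scaling), Sox4 (-0.74) and Bcl11b (-0.40). Only 5 of the 17 differences were positive, and the list median of -0.12 lay at the 0.345th percentile, or at the 12.4th among the 5 members above a 75th percentile level filter. Among 8 measured B lineage genes, Vpreb1, part of the surrogate light chain, was 2.06-fold higher (2.14 and 4.36; 0.94 on the log2 scale under 75th percentile scaling, below 2-fold). The list median was -0.16 (1.84th percentile), with Ebf1 at -0.12 and Pax5 at -0.32.

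Cytokine signalling genes showed large single differences, while their lists lay within the range of matched lists. Of 14 measured cytokine receptor and JAK-STAT genes, Il21r was higher and Il2ra lower by 2-fold or more. The list median of 0.08 lay at the 35.6th percentile and was -0.03 under 75th percentile scaling; with dimmer genes let in by a 25th percentile level filter it was 0.20 over 22 genes (95.74th percentile). Il7r, the interleukin 7 receptor, was 1.27-fold higher (11.5 and 14.4). In the list of SOCS and other feedback inhibitors, Socs3 (0.764 and 3.33) and Socs1 (3.65 and 13.5, 3.72-fold) were the 2 of 16 measured genes past 2-fold, both higher. Both encode inhibitors of cytokine receptor signalling. The remaining 14 lay within 2-fold, with Socs4 at 0.37 and Socs6 at 0.11. The list median of 0.07 was at the 29.8th percentile, and was -0.04 under 75th percentile scaling.

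Cell cycle genes were mostly slightly higher than other genes of the same level. In the list of G1 cyclins, CDKs and E2F genes, 12 of 14 measured differences were positive, with a median of 0.35 (99.84th percentile). Ccne2, which encodes cyclin E2, was 2.41-fold higher (16.7 and 39.7) and Ccne1 had a difference of 0.96, whereas Cdk6 was lower. None of 28 DNA replication genes passed 2-fold, yet 27 had positive differences. Their median of 0.29 lay at the 99.99th percentile and exceeded that of matched lists by 0.17. Mcm2, part of the replicative helicase, had the largest difference (1.53-fold). Of 21 mitosis genes, 20 had positive differences, with a median of 0.24 (98.92nd percentile, or the 97.45th, inside the central 95%, with the level filter at the 75th percentile); the largest was Prc1 (1.46-fold). These counts and medians depend on the scaling: with equal 75th percentiles, 23 of the 28 replication genes and 14 of the 21 mitosis genes had positive differences, and the medians were 0.18 and 0.13. All 3 measured CDK inhibitors had positive differences: Cdkn1a (p21) was 2.04-fold higher (1.23 and 2.48; 0.92 on the log2 scale under 75th percentile scaling), Cdkn1c stood at 0.72 and Cdkn2c at 0.24. Their median of 0.72 (99.61st percentile) rests on so few genes that it fell to 0.48 when the level filter was set at the 25th percentile, and only Cdkn2c was left at the 75th. The 5 measured genes with the prefix Cdkn, some of them outside the CDK inhibitor list, had a median of 0.24 (86.8th percentile). The 7 with the prefix Mcm had one of 0.28 (96.3rd percentile). Both of these prefix groups lay inside the central 95%. The 13 genes with the prefix Cdk had a median of 0.28 at the 98.15th percentile, outside it. After Benjamini-Hochberg adjustment over all prefix groups the value for Cdk was 0.71. All of these groups were chosen after the data were seen.

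Stress, death and interferon genes as groups lay within the range of matched lists in the main setting. Gadd45a, a growth arrest gene, was 2.40-fold higher (15.2 and 36.2) and the only member of the immediate-early and heat shock list past 2-fold, among 13 measured (79.1st percentile of the list). With the level filter at the 75th percentile 9 of its genes remained, with a median of 0.39 rather than 0.17, at the 99.665th percentile. No apoptosis gene among 17 passed 2-fold; Bid, a BH3-only gene, was 1.90-fold higher, and the list was at the 77.8th percentile. Isg20 was 2.11-fold higher and the only one of 10 measured interferon response genes past 2-fold (27.9th percentile of the list; 0.97 for Isg20 on the log2 scale under 75th percentile scaling).

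Several lists lay below matched lists without any member past 2-fold in the main setting. The chemokine receptor, homing and adhesion list had a median of -0.28 over 9 measured genes (0.02nd percentile), with Cd53, a tetraspanin, 1.87-fold lower (-1.01 on the log2 scale under 75th percentile scaling, past 2-fold); the 4 members above a 75th percentile level filter had a median of 0.0097. Glycolysis genes had a median of -0.07 over 13 genes (0.70th percentile), led by Aldoa (1.45-fold lower). Cholesterol synthesis genes had a median of -0.04 over 16 genes (1.24th percentile), led by Hmgcs1 (1.41-fold lower); after loess on level that list was at the 4.27th percentile, inside the central 95%. The ribosomal protein list had a median of -0.01 over 37 genes (0.385th percentile, or the 4.87th after quantile normalization). Many of its members lay near the top of the intensity range, and Rpl19 held the control array's maximum of 529. Whether differences are compressed there was not tested. The housekeeping list had a median of -0.04 over 14 genes (0.48th percentile). All 38 measured genes with the prefix Rpl had a median of 0.03 (5.97th percentile) and the 23 with the prefix Rps, of which 3 are kinases, a median of 0.01 (6.40th percentile), so these wider groups, chosen after the data were seen, lay inside the central 95%. In the main setting, the largest differences in the ribosomal protein and housekeeping lists were Rpl22, 1.31-fold higher, and Gusb, 1.34-fold lower. Next to Rpl22 in size came Rps19, 1.29-fold lower. The medians of the glycolysis, cholesterol, ribosomal protein and housekeeping lists lie close to 0 with the scaling used and are low relative to the other measured genes, whose median was 0.11. With equal 75th percentiles they were -0.18, -0.15, -0.12 and -0.15, with positive differences in 2 of 13, 2 of 16, 4 of 37 and 4 of 14 genes. In all, 13 of 21 lists lay outside the central 95% of matched random lists, 6 above and 7 below. These lists are not independent of one another. The glycolysis and housekeeping lists share Gapdh and Pgk1, and the B lineage and the chemokine receptor, homing and adhesion lists share Cd24a.

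Markers of other cell types were mostly under the level limit on these arrays. None of the NK and cytotoxic markers was measured. Of the myeloid markers, 2 of 18 with a named probe were measured, with Itgam at 0.866 and 1.44 (1.68-fold higher). Of the erythroid markers, Tfrc and Car1 were measured, with differences of -0.13 and -0.10. The 3 measured fibroblast and packaging cell markers were Vim (1.58-fold lower), Sparc (0.19) and Thy1 (0.39), of which T cells also express Thy1 and Vim; the list lay at the 66.0th percentile.

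**Figure D2:**
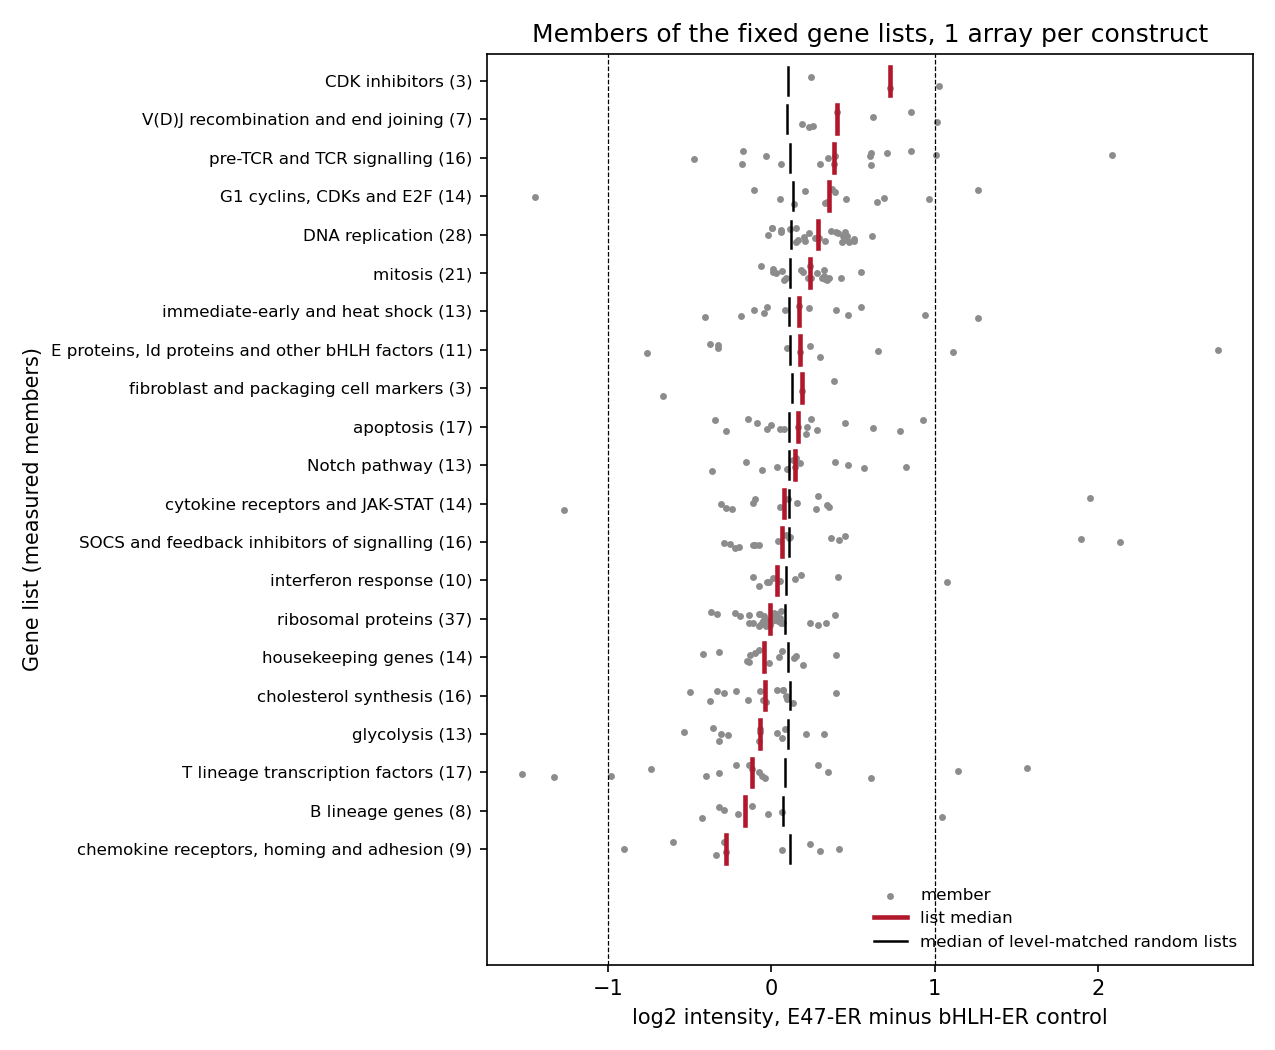
Log2 differences between the E47-ER and bHLH-ER arrays (horizontal axis) for the measured members of the 21 lists with a percentile (rows, number of measured members in brackets), with 1 grey point per gene, a red bar at the list median and a black bar at the median of level-matched random lists. Dashed lines mark 2-fold. The DNA replication genes cluster around 0.29, while the T lineage transcription factors spread from -1.53 to 1.57.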

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

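Of the tests in this part, the one on a level-dependent trend in the 2-fold calls was set before its result was seen, and so was the entry on any other difference between the cultures or arrays; the others were chosen after the results were seen.

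Probes without a gene name, which the comparison of genes does not use, also carried differences. Of 4184 measured unnamed probes, 40 were at least 2-fold brighter with E47-ER and 103 at least 2-fold dimmer; 83 of the 103 belong to the sets described next. Over all measured probes, named or not, the counts were 115 and 118. Among unnamed probes outside the sets they were 40 and 20, and counted around the median of those probes 32 and 21, a share of 60.4% higher with an exact 95% interval from 46.0%, so the unnamed probes do not decide whether the calls split unevenly. Among named genes 83.3% of the calls were higher. Symmetric noise that is independent between genes would split calls evenly around the middle of the genes. Counted around their median, 52 were higher and 24 lower (68.4%, interval from 56.7%), so such noise does not account for all of the imbalance. Noise shared by several genes is not covered. The intervals in this paragraph count each gene or probe as independent and hold no spread between cultures or arrays. A level-dependent trend between the arrays does not account for all of it either, since 73.7% of the named calls were still higher after loess on level (95% interval from 62.3%). Part of it depends on the scaling, as equal 75th percentiles gave the same 52 and 24. With 1 array per group, E47 activity and any other difference between the 2 cultures or arrays cannot be told apart.

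Sets of consecutive unnamed probes were much brighter on the control array. Runs of 6 consecutive unnamed probes above the level limit, with levels within an SD of 0.25, were found 15 times, and in none of 100 shuffles of the unnamed probes. One sequence spotted 6 times is consistent with this, and the log2 differences within sets had a pooled SD of 0.23, against 0.32 among other unnamed measured probes. The median SD of a set was 0.11, but 2 of the 15 sets spread more than those other probes. Of the 15 sets, 14 were at least 2-fold brighter on the control array, with differences from -2.22 to -1.31, while the set of probes 19911 to 19916 stood at -0.26. The median over all 15 was -1.72, or 3.29-fold, at control intensities from 2.83 to 91.5. Such sets could be controls for RNA added to the labelling reactions in unequal amounts, but no source here says what the probes detect. Equal additions with more labelled cell RNA on the E47-ER array would look alike. The 2 cannot be told apart from these values, because both would shift the sets in the same direction. The choice matters for the directions given in the report: with the sets made equal instead of the array medians, a calculation added after the data were seen, 14 of the 15 lower genes would have positive differences and none would be 2-fold lower, while 5519 of the 5563 measured genes would be at least 2-fold higher. The directions in the report are thus relative to the other genes on the arrays.

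The lists of DNA replication, G1 and mitosis genes lay above matched lists together. Loess on level lowered the medians, from 0.29 to 0.17 for replication, from 0.35 to 0.24 for G1 and from 0.24 to 0.13 for mitosis genes. It shifted the measured genes as a whole by a median of -0.099. The lists stayed above matched lists, at the 99.99th, 99.68th and 98.825th percentiles. Loess shifts genes of like level by nearly the same amount, and the random lists are matched on level. The percentiles could therefore change only a little, and their staying high is no further check. The size of the medians goes with the scaling. No value here decides whether a difference in growth between the 2 cultures unrelated to the construct lies behind it, since each construct has 1 array, and E47 activity and such a difference cannot be told apart.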

How the results depend on the processing

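The counts of 2-fold calls depended mainly on the level filter and the size rule. Against 90 genes (75 higher, 15 lower), no level filter gave 916 (496 and 420), a filter at the 25th percentile 182 (129 and 53) and one at the 75th percentile 29 (25 and 4). The rules of 1.5-fold, 3-fold and 2.5 times the local spread gave 370 (301 and 69), 22 (21 and 1) and 352 (289 and 63). Scaling to the 75th percentile raised the lower count to 24. The higher calls made up 54.1% without a level filter, 70.9% at the 25th percentile, 68.4% with the 75th percentile scaling and 74.3% and 73.7% with quantile and loess normalization. Without a level filter the SD between probes of one gene was 0.83, so dim probes limit what can be called. The other scalings, the brightest probe, the floor, the higher of both arrays as filter and, added after seeing the data, leaving out the repeated sets of unnamed probes kept the total between 74 and 109. Each of the 51 measured named genes has 1 probe, so the level filters and the brightest probe left its value as it was, and all other settings except quantile and loess normalization shifted every named gene by the same amount (-0.11 at most). Quantile and loess normalization could move these genes apart; they changed the values by -0.11 to 0.0048 and by -0.12 to 0.0011, less than the SD between probes. The number of lists outside the central 95% ranged from 9 to 13. These counts do not share a denominator. Without a level filter every list got a percentile, while the 9 came with the 75th percentile filter, where several lists had too few members. No centring and 75th percentile scaling shift all genes alike, so they could not change the percentiles. Of 252 list medians, 10 moved by more than that SD and 12, from 6 lists, changed sign. Of the lists outside the central 95%, only the chemokine receptor, homing and adhesion list did so, at 0.0097 with 4 genes above the 75th percentile filter (16.8th percentile). Of the others, cytokine receptors (-0.03), SOCS and feedback inhibitors (-0.04) and interferon response (-0.07) were negative with 75th percentile scaling, and also with quantile and loess normalization. The bHLH list (-0.04, 4.48th percentile) and the fibroblast list (-0.14) were negative with the 75th percentile filter. With that filter the T lineage factors (12.4th) and mitosis genes (97.45th) lay inside the central 95%, and the immediate-early and heat shock list (99.665th) lay outside it. B lineage genes (2 members left) and CDK inhibitors (1 left, at 0.24 against a list median of 0.72) got no percentile there. Inside it were also cholesterol synthesis genes with quantile (2.93rd) and loess (4.27th) normalization and ribosomal protein genes with quantile normalization (4.87th). Restricting to probes called present was not run, since the table used here carries no detection calls. No replicate could be left out, and no paired analysis was possible because each construct has 1 array.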

Other observations

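Genes outside the lists and the naming rule were looked through after their values were seen. No group was tested here, and these are single genes. Higher with E47-ER were the matrix protease Mmp12 (3.52-fold), the integrin alpha 6 chain Itga6 (3.37-fold), the growth factors Pdgfa (3.33-fold), Pgf (2.71-fold) and Bmp7 (2.30-fold), and the adhesion molecule Mcam (2.65-fold). The transcriptional regulators Gfi1b (3.28-fold), Xbp1 (3.14-fold; intensities 8.12 and 25.3) and Tle3 (2.30-fold) were also higher. Among lower genes, Cd160 was 2.09-fold and the LIM-domain gene Lmo4 2.05-fold lower (24.9 and 12.04). Ifi204, of the same family as Ifi202b, was 1.76-fold lower, and Ms4a6d, of the same family as Ms4a6b, 1.98-fold lower. Gfi1b and Pdgfa had control intensities of 0.622 and 0.801, under the level limit, and Ms4a6d was under it on the E47-ER array (0.955).

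A search over all 158 groups of measured genes that share the letters of their symbol and have at least 5 members gave a negative result. None stood apart from level-matched random lists after Benjamini-Hochberg adjustment, and 8 did so at an unadjusted share of random lists under 0.05, about as many as chance gives. The prefix Ccdc came first, with a median of 0.29 over 14 genes (adjusted value 0.71).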
